A study of Mus musculus with 72 samples.

How the data were processed

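Whole brain and whole liver of male mice of the inbred strains C57BL/6J (B6), DBA/2J (D2) and 129S2 had been taken at E14.5, P1, P7 and P90 and hybridised to Affymetrix arrays, with 3 arrays in each of 24 groups. The groups were taken from the sample labels. Per the labels, RNA had been extracted with TRIzol and RNeasy columns and labelled with biotin after a single round of cDNA synthesis. The deposited values are log2 RMA signals of 45101 probe sets, made by the authors with a version of RMA that is not given. The array medians ran from 5.03 to 7.30 log2 units over tissues and stages. Of the values of a pair of arrays, 1.55 to 4.35% were equal to the last digit when both came from the same tissue and stage and 0 otherwise. The authors had therefore normalized 8 sets of 9 arrays apart, and a difference between sets cannot be tested against the spread within them. Planned limma tests between stages and between tissues were replaced by sizes without p-values. Strains and their interactions with stage or tissue were tested. Strain differences lie within sets. An interaction compares such differences across sets, so a scale that differs between sets could change it.

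Of the probe sets, 34958 carried exactly 1 gene symbol, 932 carried several and 9211 none. Each of 18194 genes was represented by its probe set with the highest mean over 72 arrays, and 9012 genes had at least 2 probe sets. Genes entered a comparison when their highest group mean exceeded the median of all values (6.66), which left 14181 genes in brain, 13145 in liver and 15071 in both together. Strain differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit with a mean for each group, eBayes, tests two-sided), with all 36 arrays of a tissue in the fit, or all 72 for the interaction with tissue. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold of at least 1.5, for F tests with the fold taken from the largest difference. For stages and tissues, the arrays of a tissue (or all arrays) were quantile normalized, and a gene was counted when it was at least 2-fold apart in the same direction in each of 3 strains.

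Before the data were examined, 40 gene lists of cell types, pathways and loci known to vary in structure or sequence among laboratory mice were fixed, together with the thresholds, the rule for naming genes and most alternatives. Lists were tested between strains with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, with adjustment within each tissue (69 tests in brain, 96 in liver). Between stages and tissues, their medians were placed among 10000 random lists matched for expression. Neighbouring genes were those adjacent in the RefSeq annotation of the mouse reference assembly, which placed 18029 genes, with starts within 1 Mb. Pairs called in the same direction were counted and compared with 10000 permutations of the calls, one-sided.

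The rule for named genes took, per tissue, the 12 highest and 12 lowest genes between P90 and E14.5, the 5 highest and 5 lowest of each strain pair with the same sign at 4 stages and the 12 highest F values of the interaction with stage. It also took the 10 highest and 10 lowest genes between tissues, members of neighbour runs of at least 3, list members with the largest absolute change among those called, and members of the locus lists at 2-fold or more. For stages, a 2-fold minimum in each strain took the place of the p-value in that rule. Clone-like symbols were counted and not named, except inside neighbour runs. Strain labels were checked on 400 marker probe sets and sex labels on Y-linked transcripts and Xist, and no pair of arrays was identical, with a highest correlation across probe sets of 0.998.

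Alternatives were no filter and a stricter filter (8.40), all probe sets, the mean of the probe sets of a gene, another quantile normalization, median centring, a trended and robust variance, array weights, only the arrays compared, a replicate block, no fold minimum, agreement of a second probe set, other distances between neighbours, like-named neighbours left out, and each array left out. Chosen after seeing the data were a filter at the median of each set, the values as deposited for stages and tissues, list tests at each stage with arrays left out of them, and counts without a pair of doubtful arrays. Other splits of the arrays (60 per result, the real one included) served as a check against chance. On simulated data with 50 changed genes per fold size, the strain test called 48% of 1.5-fold and 100% of 2-fold differences in brain and 0 of 13981 unchanged genes, and 2-fold minima in each strain found 16% of genes with a true 2-fold difference and 100% of those with 3-fold. The 48% and 16% belong to true folds equal to the minimum, which sets them in large part. The simulated noise was independent between genes, with 1 SD per gene over all stages and no outlying arrays. The real data need not share these properties, so the shares do not measure error in them. Data were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.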

Results

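Gene expression was measured on 72 Affymetrix arrays hybridised with RNA from whole brain and whole liver of male mice. The animals came from 3 inbred strains, C57BL/6J (B6), DBA/2J (D2) and 129S2, and were taken at 4 stages, E14.5, P1, P7 and P90. Each of the 24 combinations of strain, tissue and stage had 3 arrays, a number that limits the precision. All arrays carried the Y-linked transcript Eif2s3y at 1.36 to 4.32 log2 units above the median of their set. Kdm5d and Uty reached down to -0.12 and -0.99 in brain and to 0.67 and 0.49 in liver. Xist lay between -0.65 and 0.42 in brain and between -0.39 and 1.07 in liver. The deviations of 72 of 72 arrays correlated best with the profile of their own strain, but P90 brain replicate 2 of 129S2 did so weakly, with r = 0.35 across 400 marker probe sets that are not independent replicates. The median array value lay between 7.26 and 7.30 log2 units in E14.5 brain and between 5.03 and 5.08 in P90 liver. The values had been normalized separately for each tissue and stage, so stages and tissues are compared by size only and strains by tests within tissues.

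The stage comparison asked which transcripts set the embryonic brain apart from the adult brain. Among the 12 named genes lowest at P90 were Rrm2, a subunit of ribonucleotide reductase, at -6.69 ± 0.43 on the log2 scale (P90 minus E14.5, mean ± SD over 3 strains, 3 arrays each), Ube2c at -6.25 ± 0.53 and the neuronal transcription factor Sox11 at -5.51 ± 0.09. Thy1, a surface protein of mature neurons, was 7.31 ± 0.21 higher at P90, followed by the neurotensin receptor Ntsr2 (6.11 ± 0.18), Fam107a (6.09 ± 0.49), the cytokine Il33 (6.00 ± 0.54), the kinase Ptk2b (5.88 ± 0.14) and the astrocytic water channel Aqp4 (5.70 ± 0.19). Cracdl, Abhd3, Necab1, Itpka, Rasgrp1 and Phyhip were between 5.53 and 5.94 higher. The embryonic globin Hbb-y was at -7.60 ± 0.55, and Gpc2, Uhrf1, Ect2, Cdca8, Bub1, Ptx3, Cdca5 and Aplnr lay between -6.17 and -5.58. For 22 of these 24 genes the lower mean lay under the filter of 6.66, such as Thy1 at 5.46 in E14.5, and the files hold no detection calls, so the sizes and their order are not exact.

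Of 32 cell cycle genes, 30 were at least 2-fold lower at P90 than at E14.5 in every strain, with a median of -3.81. Of 22 markers of neural progenitors and new neurons 20 were lower (median -2.83), among them Neurog2 (-5.33 ± 0.31) and Igfbpl1 (-4.95 ± 0.09). Astrocyte markers were higher in 13 of 16 cases (median 3.32), myelin genes in 16 of 18 (median 2.86), synapse genes in 21 of 26 (median 2.46) and microglial genes in 9 of 12 (median 1.77). Examples were S100b (4.85 ± 0.05), the myelin protein gene Mog (5.44 ± 0.27), the postsynaptic Nrgn (5.23 ± 0.21) and the microglial purinergic receptor P2ry12 (2.93 ± 0.31). Each of these 6 medians lay at percentile 0 or 100 of 10000 random lists matched for expression. Immediate early genes such as Arc (4.74 ± 0.38) and Egr1 (4.40 ± 0.48) were higher in 10 of 22 cases, and clock genes such as Dbp (3.66 ± 0.61) in 8 of 16, with 1 lower. Fetal and imprinted growth genes were lower in 11 of 14 cases (median -1.98). The cell cycle genes already had a median of -1.95 between E14.5 and P1, with 28 of 32 lower, whereas myelin genes were mostly higher between P7 and P90 (14 of 18, median 2.15). Interferon response genes had a median of 0.81 and oxidative phosphorylation genes of 0.57, and these turned to -0.05 and -0.03 on the values as deposited. There the medians of immediate early, clock and microglial genes fell from 0.80 to 0.09, from 1.33 to 0.61 and from 1.77 to 0.99.

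In all, 1716 of 14181 brain genes were at least 2-fold higher and 2260 lower at P90 than at E14.5 in each strain. The smaller steps gave 637 higher and 455 lower (P1 minus E14.5), 175 and 48 (P7 minus P1) and 569 and 1393 (P90 minus P7). The median of all brain genes lay at -0.20 between E14.5 and P90 after quantile normalization and at -0.96 on the values as deposited, on which 6914 genes differed and 6118 of them were lower. The medians of bacterial spike-in probe sets at P90 lay 0.22 above E14.5 in brain and 0.24 in liver, with SDs of 0.47 and 0.57 over 18 probe sets, so differences of that size cannot be read. On the values as deposited the spike-in medians lay at -0.34 in brain and -0.47 in liver.

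**Figure D1:**
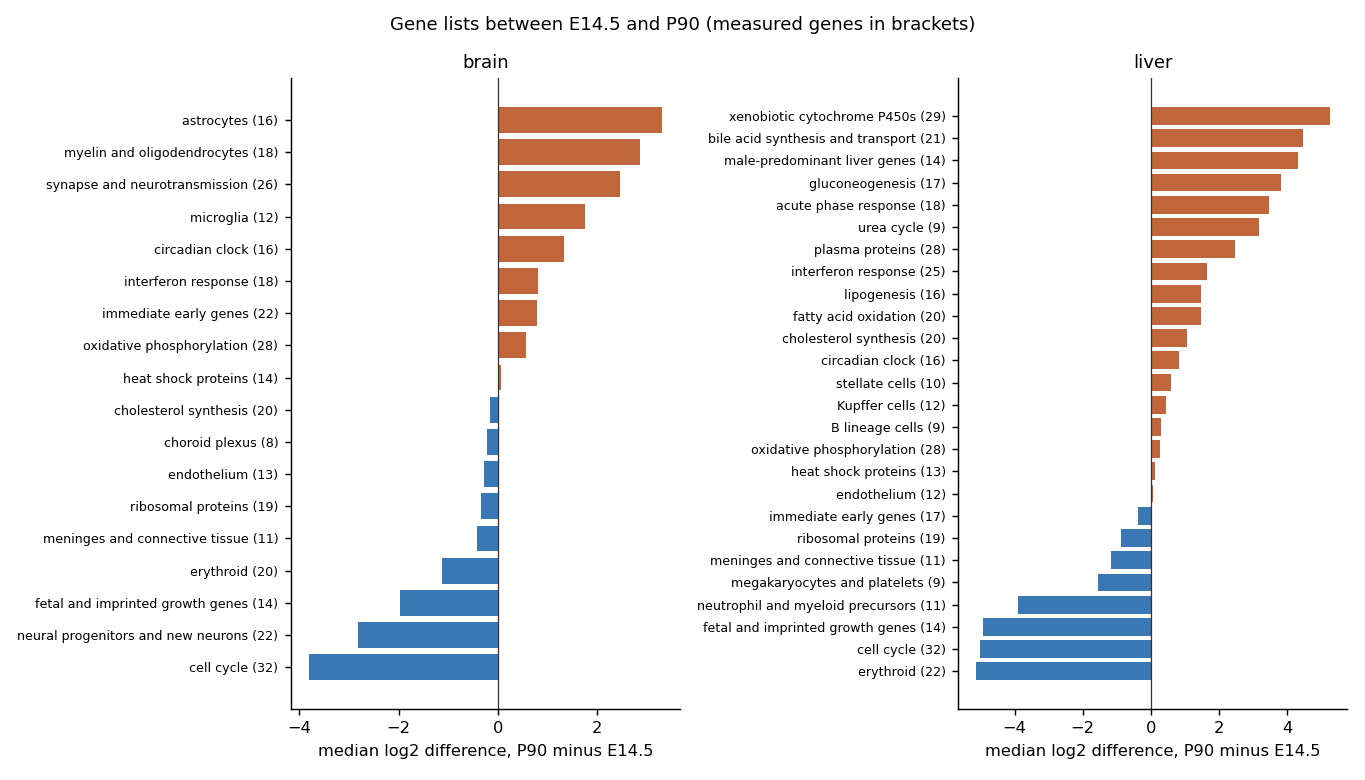
Each bar is the median log2 difference between P90 and E14.5 over the measured genes of a list, in brain (left) and liver (right), after quantile normalization within the tissue. Cell cycle genes stand at -3.81 in brain and -5.01 in liver, and cytochrome P450 genes at 5.26 in liver.

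The liver passes from a blood-forming to a metabolic organ in this interval, and the same comparison was made there. Among the 12 named genes lowest at P90 were the Rhesus glycoprotein Rhag at -9.55 ± 0.08, Hemgn at -9.49 ± 0.13, the anion exchanger Slc4a1 at -8.47 ± 0.06, Hbb-y at -7.85 ± 0.32, alpha-fetoprotein Afp at -8.63 ± 0.24 and Bex1 at -9.43 ± 0.30. Among the 12 named as highest were the major urinary protein Mup3 at 10.68 ± 0.05, tryptophan dioxygenase Tdo2 at 10.32 ± 0.16, Cyp2f2 at 9.91 ± 0.19, Cyp3a25 at 9.50 ± 0.24 and the bile acid enzyme Cyp7b1 at 8.81 ± 0.34. Mug1, Orm1, Ces1c, Mup10, Aldh1a1, Cyp1a2 and Lrg1 lay between 8.34 and 9.39, and Trim59, Kel, Bex4, Uhrf1, Cdc6 and Cd24a between -8.01 and -7.39. The lower mean lay under the filter for 23 of these 24 genes, with Mup3 at 3.52 in E14.5 and Rhag at 3.19 in P90, so these sizes are not exact either.

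Of 22 erythroid genes 21 were at least 2-fold lower at P90 (median -5.13), and so were 32 of 32 cell cycle genes (median -5.01), 14 of 14 fetal growth genes and 10 of 11 neutrophil and myeloid precursor genes (median -3.91), such as Mpo at -5.88 and S100a8 at -5.99. Xenobiotic cytochrome P450 genes were higher in 23 of 29 cases and lower in 3 (median 5.26), bile acid genes in 19 of 21 (4.48), male-predominant genes in 11 of 14 (4.33), gluconeogenesis and amino acid genes in 17 of 17 (3.84), urea cycle genes in 9 of 9 (3.19) and plasma protein genes in 22 of 28 (2.47). Part of this was present at birth. Fatty acid oxidation genes were higher at P1 than at E14.5 in 19 of 20 cases (median 1.89), with Ehhadh at 4.89 ± 0.30 and Cpt1a, the gate of mitochondrial fatty acid import, at 3.78 ± 0.37, and gluconeogenesis genes in 14 of 17. Kupffer cell genes were higher at P1 in 7 of 12 cases (Cd163 3.53 ± 0.59) and B lineage genes in 5 of 9 (Cd79a 2.63 ± 0.55). Neutrophil genes were all lower at P90 than at P7 (11 of 11, median -4.91), while male-predominant genes were higher in 10 of 14 cases (2.33) and cholesterol synthesis genes in 14 of 20 (1.73). As deposited, the medians of male-predominant and cholesterol synthesis genes were 1.51 and 1.02, and after median centring 2.85 and 2.36.

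In liver 1854 of 13145 genes were at least 2-fold higher and 2609 lower at P90 than at E14.5, with 1213 and 734 for P1 minus E14.5, 172 and 69 for P7 minus P1, and 500 and 1628 for P90 minus P7. The median of all liver genes was -0.21 after quantile normalization and -1.70 as deposited, where 648 genes were higher and 8736 lower. The 1628 lower against 500 higher genes between P7 and P90 rest on this choice, since centring each array on its median gave 1137 higher and 1297 lower and moved the median of all genes from -0.16 to 0.12.

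Brain and liver were compared stage by stage to show the extent of tissue identity. Averaged over 4 stages, the synaptic vesicle fusion gene Snap25 was 9.10 higher in brain, followed by the adhesion molecule Chl1 (8.49), the GABA-synthesising enzyme Gad1 (8.30), Elavl2 (7.98), Snap91 (7.97), the stem cell factor Sox2 (7.92), Rab6b (7.82), the cannabinoid receptor Cnr1 (7.81), Kif5c and Neurod6 (both 7.68). Kininogen Kng1 (-8.19), Ambp (-8.16), Bhmt2 (-8.08), the fatty acid binding protein Fabp1 (-7.98) and the fibrinogen chains Fgg, Fga and Fgb (-7.98 to -7.88) led on the liver side, with Ugt2b5, Apoc2 and Cyp2d10 between -7.82 and -7.74. The files hold no detection calls for the tissue with less signal, so these sizes and their order are not exact. At E14.5 progenitor markers were higher in brain in 21 of 22 cases (median 5.15), and erythroid genes were lower in 17 of 22 (-3.72), neutrophil genes in 10 of 11 (-4.33) and plasma proteins in 26 of 28 (-5.43). By P90 synapse genes were higher in 25 of 26 cases (5.36), with Snap25 at 10.70 ± 0.08, and plasma proteins were lower in 27 of 28 (-8.26) and cytochrome P450 genes in 24 of 29 (-7.20). The genes at least 2-fold apart in each strain numbered 2472 higher and 2459 lower in brain at E14.5, 2880 and 2913 at P1, 2945 and 3038 at P7, and 3200 and 3038 at P90. At all 4 stages 1532 genes were higher in brain and 1091 in liver.

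The strain comparison asked how far the transcriptomes of 3 inbred genomes differ in the same tissue. In brain, averaged over 4 stages (12 arrays per strain, log2 difference ± SE), D2 exceeded B6 in Stab2, a scavenger receptor of sinusoidal endothelium (2.54 ± 0.07, 5.80-fold), Slc25a31 (2.47 ± 0.16), Hddc3 (2.17 ± 0.06), the somatostatin receptor Sstr1 (2.13 ± 0.10) and Tmem87a (2.11 ± 0.08). It fell below B6 in Soga3 (7.99-fold, SE 0.10 on the log2 scale), Mir1931 (-2.85 ± 0.13), Pdxdc1 (-2.78 ± 0.07), Tmem267 (-2.70 ± 0.29) and Sbsn (-2.58 ± 0.06). Between 129S2 and B6, Tmem87a (2.18), Hddc3 (2.15), Sstr1 (1.98), Wdfy1 (1.68) and Adat2 (1.54) were higher, and Rpgrip1, a ciliary protein gene (-3.21 ± 0.10, 9.24-fold), Mir1931 (-2.80), Tmem267 (-2.65), the lysosomal galactosylceramidase Galc (-2.51 ± 0.21) and the long noncoding RNA Rmst (-2.36 ± 0.09) were lower. Soga3 (2.81), Pdxdc1 (2.77), Sbsn (1.95), the ceramidase Acer3 (1.86) and Fam168a (1.72) were higher in 129S2 than in D2, and Stab2 (-2.61), Galc (-2.55), Rpl14 (-1.59), Pcdhb9 (-1.57) and the kainate receptor subunit Grik1 (-1.57) were lower. The same sign at all 4 stages was a condition for naming these genes, and their adjusted p ran from 9.4e-23 to 6.1e-08. Their sizes could still vary with stage, such as Sstr1 in D2 against B6 at 0.56 at E14.5 and 2.77 at P1.

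Of 14181 brain genes, 178 differed between D2 and B6 by at least 1.5-fold (74 higher and 104 lower in D2), 179 between 129S2 and B6 (68 and 111) and 151 between 129S2 and D2 (71 and 80). Differences of at least 2-fold numbered 59, 51 and 45. A second probe set existed for 77 of the D2 and B6 genes with several usable probe sets, and it was called in the same direction for 32 of them (41.6%). It was called for 28 of 79 genes of 129S2 and B6 (35.4%) and 18 of 61 of 129S2 and D2 (29.5%). Averaging all probe sets of a gene cannot move a gene with a single probe set. With it, 36 of 123 named strain results of both tissues moved by more than 1.5 times. Among them Hddc3 shrank to 1.07 and Soga3 to -1.73 in D2 against B6, Galc to -0.78 in 129S2 against B6, and Pdxdc1 was no longer called. In 129S2 brain, Rmst shrank to -1.31 and Wdfy1 to 1.05 against B6, and Fam168a to 0.84 and Grik1 to -0.71 against D2.

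In liver the D2 difference was led by Ifi202b, an interferon-inducible gene (3.75 ± 0.07, 13.4-fold over B6), Xaf1 (2.90 ± 0.11), the adaptor gene Pik3ap1 (2.65 ± 0.06), Hddc3 (2.48 ± 0.08) and Ccnb1ip1 (4.94-fold, SE 0.14). Mndal (-3.16 ± 0.11), angiogenin Ang (-2.90 ± 0.06), Zfp874a (-2.75 ± 0.07), Tmem267 (-2.66 ± 0.12) and Pdxdc1 (-2.64 ± 0.06) were lower in D2. In 129S2, Pik3ap1 (2.94), the phosphodiesterase Gdpd3 (2.69), Abhd1 (2.61), Hddc3 (2.41) and cathepsin E, Ctse (2.38), exceeded B6, while Rpgrip1 (-2.98), Ang (-2.87), the cytochrome P450 gene Cyp2b9 (-2.77), Zfp874a (-2.72) and Tmem267 (-2.54) were lower. Against D2, 129S2 was higher in the peptide transporter Slc15a2 (2.87 ± 0.17), Pdxdc1 (2.75), Abhd1 (2.74), Gdpd3 (2.71) and Mndal (2.27) and lower in Cyp2b9 (-2.86), Rassf4 (-2.82), the melanin enzyme gene Dct (-2.35), Cyp2c37 (-2.02) and Ifi202b (-1.98). Adjusted p for these genes ran from 8.3e-27 to 3e-12. The SE reflects spread between arrays, and some of these averages varied widely between stages. Ccnb1ip1 in D2 against B6 fell from 4.97 at E14.5 to 0.48 at P90, whereas Hddc3 stayed between 2.24 and 2.67. Ctse in 129S2 against B6 was 0.24 at P7 and 4.09 at P90, and Dct in 129S2 against D2 was -0.11 at E14.5 and -5.54 at P90. With the probe sets of a gene averaged, Xaf1 in D2 shrank to 0.78, Pik3ap1 to 1.21 and Ang to -1.49, Ctse in 129S2 against B6 to 1.08 and Slc15a2 against D2 to 1.13. Pdxdc1 was no longer called (-0.22 in D2 against B6, 0.26 in 129S2 against D2). Of 13145 liver genes, 355 differed between D2 and B6 (145 higher, 210 lower), 431 between 129S2 and B6 (167 and 264) and 358 between 129S2 and D2 (190 and 168), and the 2-fold differences numbered 106, 121 and 112. The lower strain mean lay under the filter for 16 of 30 named strain results in brain and 19 of 30 in liver, so their folds are not exact.

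**Figure D2:**
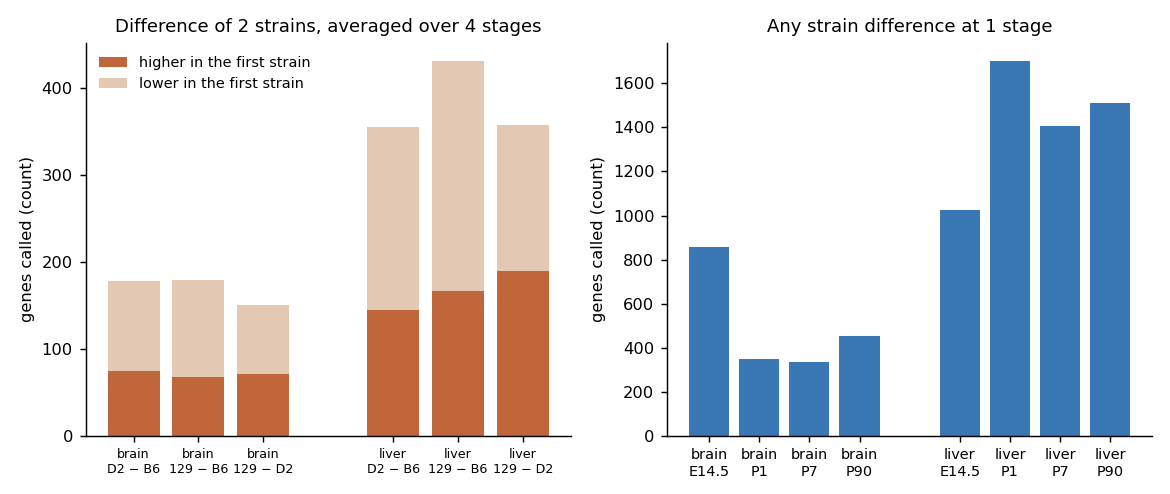
Bars count the genes called between pairs of strains over 4 stages (left, split by direction) and the genes with any strain difference at a single stage (right), in brain and liver. Liver gave more calls than brain for each pair, 355 against 178 for D2 and B6.

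The series asks how segmental copy number variation shapes tissue transcriptomes, so genes from loci known to vary in structure among laboratory mice, and genes with known coding or regulatory variants, had been listed before the data were examined. Glo1, the glyoxalase gene of a duplicated segment, was higher than in B6 in D2 brain (1.02 ± 0.07), 129S2 brain (1.35 ± 0.07), D2 liver (0.69 ± 0.05) and 129S2 liver (1.04 ± 0.05), and 3 of 3 further probe sets moved the same way. Alad, an enzyme of haem synthesis that lies in another duplicated segment, was 1.41 ± 0.08 higher in D2 brain and 1.10 ± 0.04 in D2 liver, and 0.83 ± 0.07 and 1.08 ± 0.04 higher in 129S2 brain and liver. Its 1 further probe set was called the same way in D2 and 129S2 liver but not in D2 brain. Hdhd3, the neighbour of Alad, was 1.13 ± 0.09 higher in D2 liver, 0.85 in D2 brain and 0.84 in 129S2 liver. The GABA receptor subunit gene Gabra2 was higher in D2 (1.07 ± 0.07) and 129S2 brain (1.16 ± 0.07). With its probe sets averaged this was 0.65 and 0.72. Complement component Hc was lower in D2 liver than in B6 (-1.49 ± 0.07) and in 129S2 higher than in D2 (1.45). Nnt, a mitochondrial transhydrogenase, was 1.02 ± 0.08 higher in 129S2 liver and 0.96 ± 0.08 in D2 liver than in B6. The natural killer receptor gene Klrd1 was lower in D2 (-1.54) and 2-fold lower in 129S2, and the macrophage protein gene Cd5l was lower in 129S2 (-1.06) and D2 (-0.69).

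In liver, Ifi202b was 1.77 higher in 129S2 than in B6, while Ifi204 was lower in D2 (-1.41) and 129S2 (-2.26). Trim30d (-2.18 and -2.53) and Trim34a (-2.15 and -2.43) were lower in both, and so was Trim30a (-0.98 and -1.26). With its probe sets averaged, Trim30d was at -1.31 and -1.50. In brain, Trim34a was at -0.82 in both. The guanylate-binding protein genes Gbp6 (-1.50) and Gbp8 (-1.04) were lower in 129S2 than in D2, and lower than in B6 (-0.87 and -0.92). Gbp6 was 0.62 higher in D2 than in B6, and Gbp2b was higher in 129S2 than in B6 (1.08) and D2 (0.90). Among class I histocompatibility genes, H2-Q2 was lower in D2 than in B6 in brain (-1.63) and liver (-1.80) and higher in 129S2 than in D2 (1.37 and 1.91), and H2-Bl was higher in 129S2 brain (1.02 over B6, 1.23 over D2) and liver (0.68 and 0.71). H2-D1 was lower in D2 brain (-1.11) and liver (-1.20) by its main probe set, but the mean of its probe sets gave 0.17 and 0.96. In 129S2, Serpina3n was higher in brain (1.15 over B6, 0.67 over D2), and Cyp4a14 (1.23 over B6, 1.40 over D2) and Ugt2b38 (-1.36 and -1.07) differed in liver, mostly from P90 differences of 5.11, 6.34, -5.36 and -4.55. Of 32 structural genes measured in brain, 3 were higher and 3 lower in D2 than in B6 (4 and 3 adjusted over the list alone), 4 and 1 in 129S2 than in B6, and 4 and 0 in 129S2 than in D2 (4 and 1 adjusted over the list alone). Of 60 measured in liver, 6 were higher and 10 lower in D2 (adjusted p of the list 0.0259), 8 and 13 in 129S2 (0.0196), and 7 and 8 between 129S2 and D2 (0.67). The liver shifts had adjusted p = 0.518 with an estimated correlation. The list test looks for a net shift in 1 direction, so members called both ways offset each other in it. Of all 13145 liver genes, 145 were higher and 210 lower in D2 than in B6. In 129S2, 167 were higher and 264 lower than in B6, and 190 and 168 than in D2. Of 10 measured known-variant genes in liver 2 were higher and 3 lower in D2 (adjusted p = 0.0287, and adjusted p = 0.386 with an estimated correlation), and in brain Gabra2 was the 1 called member in each comparison with B6.

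Among functional groups in liver, interferon response genes were lower in 129S2 than in both other strains. In 129S2 against B6, 15 of 25 were lower, among them Oasl2 (-1.24 ± 0.13), Bst2 (-1.04 ± 0.10) and Trim30a, and Xaf1 was higher (1.69 ± 0.11), with a median of -0.65 (adjusted p = 1.21e-10, and adjusted p = 0.454 with an estimated correlation). Against D2, 16 of 25 were lower (median -0.78, adjusted p = 2.92e-15, and adjusted p = 0.335 with an estimated correlation), including Gbp2 (-1.37 ± 0.21), Xaf1 (-1.21 ± 0.11), Ifit1 (-1.16 ± 0.12) and Rtp4 (-1.09 ± 0.14). Neutrophil and myeloid precursor genes, from granule proteins of the blood-forming liver, were lower than in B6 in D2 (8 of 11, median -0.73, adjusted p = 6.49e-07) and 129S2 (6 of 11, median -0.63, adjusted p = 5.45e-07), and both had adjusted p = 0.386 with an estimated correlation. Lcn2 (-1.47 ± 0.33 in D2), S100a8 (-1.14 ± 0.17) and S100a9 (-0.91 ± 0.15) were among them. Kupffer cell genes were lower in 129S2 than in B6 in 6 of 12 cases (median -0.66, adjusted p = 2.89e-08), including Cd5l and the complement genes C1qa (-0.94 ± 0.08) and C1qc (-0.86 ± 0.07), and in D2 in 3 of 12 (median -0.48, adjusted p = 3.17e-04). These had adjusted p = 0.284 and 0.518 with an estimated correlation.

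Gluconeogenesis and amino acid genes were higher in 129S2 than in D2 in 5 of 17 cases, with Got1 at 1.04 ± 0.22, Pck1 at 0.81 ± 0.24 and Tat at 0.80 ± 0.20 (median 0.32, adjusted p = 3.17e-04, and adjusted p = 0.518 with an estimated correlation), and lower in D2 than in B6 in 2 of 17 (median -0.25, adjusted p = 0.0112, and adjusted p = 0.612 with an estimated correlation). Of 29 xenobiotic cytochrome P450 genes 6 were higher and 3 lower in 129S2 than in D2 (adjusted p of the list 0.737), and 3 and 4 in 129S2 than in B6 (0.944). Here too the list test looks only for a net shift in 1 direction. Clock genes had a median of 0.33 in 129S2 against B6 (adjusted p = 0.00156) and 0.28 against D2 (adjusted p = 0.00811), each with Dbp and Per3 as the 2 called members, and both had adjusted p = 0.284 with an estimated correlation. A further 14 liver list shifts passed the threshold with at most 2 called members each. In D2 against B6 they were megakaryocyte (median -0.22, adjusted p = 0.0287), stellate cell (0.25, 0.0105), plasma protein (-0.10, 0.00881) and cholesterol synthesis genes (-0.17, 0.0196), with Colec10 (0.59) and the sterol desaturase Sc5d (-1.41) as called members. These had adjusted p = 0.612, 0.518, 0.588 and 0.938 with an estimated correlation. In 129S2 against B6 they were megakaryocyte (-0.10, 0.0294), stellate cell (0.20, 0.0233), fetal growth (0.16, 0.0294), fatty acid oxidation (0.17, 0.0105), heat shock (-0.06, 0.0224) and ribosomal protein genes (-0.05, 0.0112). Called members were Rgs5 (1.00), Pdgfrb (0.61), Meg3 (0.74), the fasting hormone Fgf21 (0.70), Hspb1 (-0.66) and Rps6 (-1.16), and the adjusted p ran from 0.518 to 0.612 with an estimated correlation. In 129S2 against D2 they were erythroid (0.25, 0.0196), Kupffer cell (-0.24, 0.0221), urea cycle (0.25, 0.0105) and heat shock genes (-0.16, 0.00811), with C1qa (-0.67), the carbamoyl phosphate synthetase Cps1 (0.71) and Hspa1b (-0.86) called. These had adjusted p = 0.938, 0.612, 0.471 and 0.518 with an estimated correlation. In these liver lists the counts adjusted over the list alone equalled those over all genes.

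**Figure D3:**
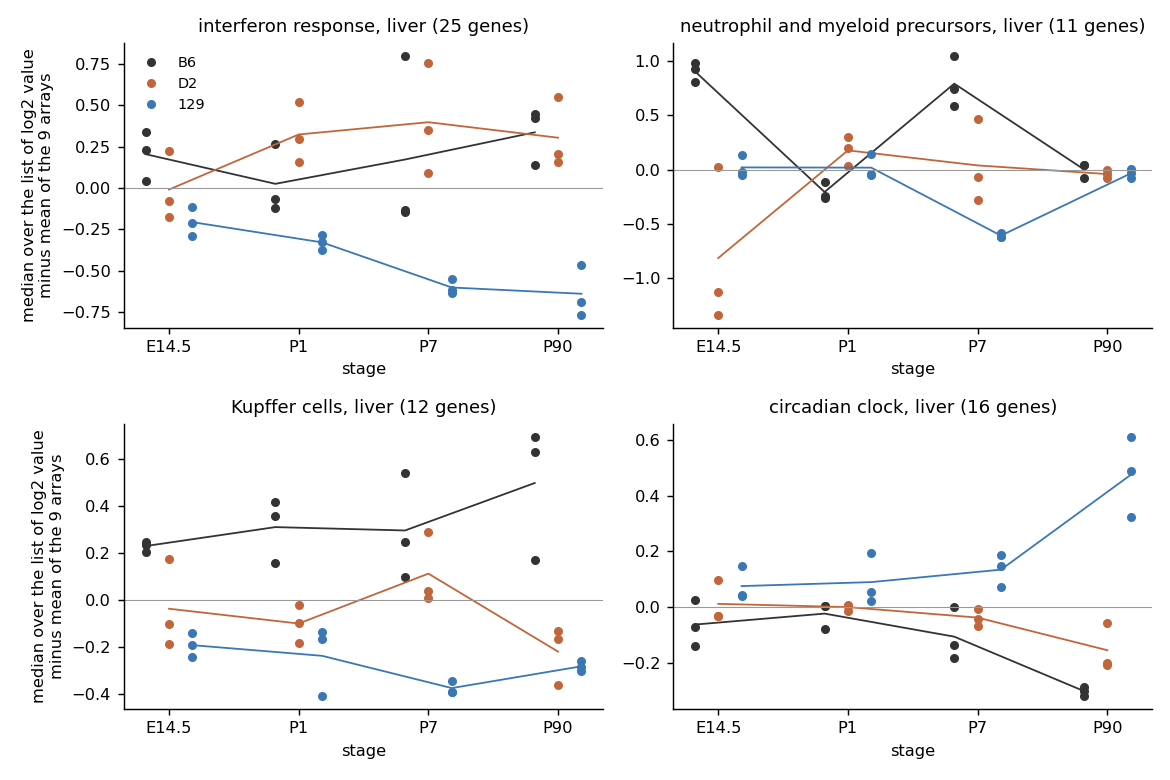
Each point is an array, and its height is the median over the list of the log2 value minus the mean of the 9 arrays of the same stage; lines join strain means. The 3 arrays of 129S2 lie below 0 for interferon response genes at every stage.

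In brain, microglial genes had a median of -0.20 in 129S2 against B6, with Ctss, a lysosomal protease, as the 1 called member of 12 (-0.67 ± 0.07, adjusted p of the list 0.00941, and adjusted p = 0.917 with an estimated correlation). Of the interferon response genes in that comparison the 1 called member, Xaf1, was higher (1.26 ± 0.12) although the median of 18 was -0.08. The other 6 brain list shifts past the threshold had medians between -0.11 and 0.13, namely synapse and immediate early genes in D2 against B6, cholesterol synthesis and heat shock genes in 129S2 against B6, and immediate early and heat shock genes in 129S2 against D2. All 8 had adjusted p = 0.917 with an estimated correlation. Over brain and liver, 35 of 165 list tests passed with the preset correlation and 0 of these with an estimated correlation.

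Many of these strain calls were common to both tissues. Tmem267, Hddc3, Pdxdc1 and Rpgrip1 are examples named in each, with nearly equal sizes in brain and liver. With its probe sets averaged, Pdxdc1 in D2 against B6 fell to -0.39 in brain and -0.22 in liver. Of 12255 genes tested in both, 75 were called in the same direction for D2 and B6 where 1.6 were expected from independent calls, 74 for 129S2 and B6 (1.7 expected) and 57 for 129S2 and D2 (1.2 expected), and 2, 1 and 2 were called in opposite directions. Both tissues were read with the same probe sets. A strain variant under a probe could therefore recur in each, which the expected numbers do not allow for and which was not tested. The strain difference itself differed between brain and liver for 681 of 15071 genes.

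Genes with a strain difference were also counted at single stages. In brain 858 genes had a strain difference at E14.5, 350 at P1, 334 at P7 and 451 at P90, and in liver 1025, 1700, 1408 and 1509. The E14.5 brain count rests partly on B6 replicate 3, without which it was 683. Without B6 replicate 1 the count was 1336. A fit to the 9 arrays of the stage alone, which borrows no spread from other stages, gave 253, and the cause of that drop was not tested. At that stage 20 of 32 cell cycle genes, such as Nusap1 (1.06 ± 0.16) and Bub1 (1.04 ± 0.19), were higher in D2 than in B6 (median 0.63, adjusted p = 2.78e-11) and 13 of 32 in 129S2 (16 adjusted over the list alone, median 0.58, adjusted p = 3.41e-14), with adjusted p = 0.705 and 0.621 with an estimated correlation. Ribosomal protein genes of B6 replicate 3 lay -0.66 from the mean of the set and cell cycle genes -1.06, and without that array 4 and 1 of the 32 cell cycle genes were called. In D2 replicate 1, meninges and connective tissue genes lay 1.24 from the mean of the set, against -0.37 to 0.15 in its other arrays. The P90 brain count was 534 without P90 replicate 2 of 129S2, and 298 with a stricter filter on low values. Brain arrays had a mean r with their own group of 0.981 to 0.993 at E14.5 and 0.995 to 0.998 at P90. The main fit applied 1 spread per gene to all stages, so counts of different stages do not rest on equal error.

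Stage by strain interactions singled out genes whose strain difference appeared, vanished or turned over. In brain the securin gene Pttg1 was 1.68 higher in D2 than in B6 at E14.5 and -3.38 at P90, with 1.67 and -3.52 in 129S2, and 2 of 2 further probe sets were also called. Gnb1, a G protein subunit gene, was 1.83 higher in both strains at P90 and at most 0.22 before, and the calcium-binding protein gene S100a5 was -2.30 and -2.29 at P90. Rmst differed most at E14.5 (-4.21 and -4.32), and so did the carbonic anhydrase-related Car8 (-1.84 and -1.72). The macrophage gene Fcrls (-1.66 and -1.84), Cfap54 (1.52 and 1.72), Efhd2 (-1.70 and -1.91) and Prune2 (1.32 and 1.33) differed most at P90, the last not when probe sets were averaged. Car8 then had a range of 0.59 in place of 2.07. Of further probe sets, 1 of 1 was called for Gnb1, 1 of 2 for Car8, 1 of 3 for Prune2 and 0 of 1 each for Neat1, Rmst and Efhd2. Neat1 reached -2.04 in D2 alone, and Gdpd3 3.46 in 129S2 alone. H2-Q2 was at -3.59 in D2 at P7 and -0.24 at P90. Adjusted p for these 12 genes ran from 1.5e-15 to 1.5e-07, and 669 of 14181 brain genes had such an interaction (1389 with array weights).

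In liver, Cyp2b9 was -4.31 at P1 and -6.53 at P7 in 129S2 against B6, but -0.21 at E14.5 and -0.04 at P90. Rassf4 stood at 5.34 in D2 against B6 at P90 and at -0.20 at E14.5. Cyp2c39 reached 5.51 and Gdpd3 5.21 in 129S2 at P90, and Cox6b2 4.27. The nicotinamide methyltransferase gene Nnmt (-3.78 in D2, -3.36 in 129S2), Adh6-ps1 (-2.49 and -2.88), Pttg1 (-2.66 and -2.30) and Fmn2 (3.15 and 2.01) separated both strains from B6 at P90, and the fatty acid elongase Elovl3 was -1.85 in 129S2. Serpina1c, an antitrypsin gene, was -2.64 in D2 and -1.46 in 129S2 at E14.5 and within 0.22 of B6 later, and Klrd1 was at -3.22 in D2 and -1.63 in 129S2 at P7 and at -0.10 and -0.07 at P90. Adjusted p for these genes ran from 1.8e-17 to 3.6e-14, and 4176 of 13145 liver genes had an interaction.

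**Figure D4:**
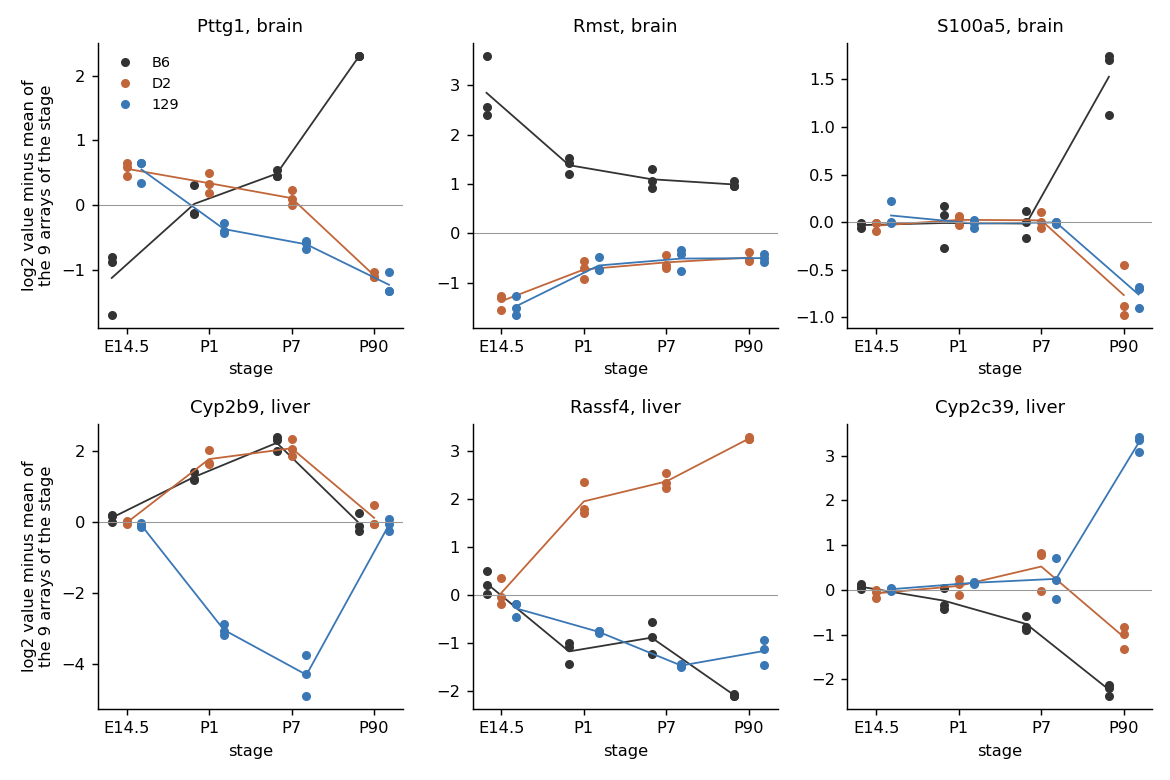
Each point is an array, at its log2 value minus the mean of the 9 arrays of that tissue and stage; lines join strain means. Pttg1 in brain passes from below the other strains to above them in B6, a D2 minus B6 difference of 1.68 at E14.5 and -3.38 at P90.

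Neighbouring genes were compared because a copy number difference would move adjacent genes together. In brain, 4833420G17Rik, Tmem267 and Ccl28 formed a run of adjacent genes lower in D2 than in B6 (-1.51, -2.70 and -0.61), and Mid1, G530011O06Rik and Erdr1 a run lower in 129S2 than in B6 (-1.57, -1.95 and -1.02) and than in D2 (-1.38, -1.72 and -0.62). In liver the interferon-inducible genes Ifi209, Ifi204 and Mndal were lower together in D2 (-1.30, -1.41 and -3.16) and 129S2 (-1.64, -2.26 and -0.89), and Snrnp25, Rhbdf1 and Mpg were higher together in D2 than in B6 (1.08, 0.67 and 0.65) and lower in 129S2 than in D2 (-0.91, -0.60 and -0.63). The serine protease genes Mcpt8, Ctsg and Gzmb (-0.71, -0.82 and -0.90) and the complement genes C1qb, C1qc and C1qa (-0.75, -0.86 and -0.94) were lower together in 129S2 than in B6. Adjacent genes starting within 1 Mb of each other were called in the same direction in 6 pairs for D2 and B6, 6 for 129S2 and B6, and 4 for 129S2 and D2 in brain, where permutations of the calls gave means of 1.09, 1.12 and 0.74 (one-sided permutation p = 9e-04, 0.0017 and 0.0068). In liver the pairs numbered 26, 37 and 22, with permuted means of 4.75, 7.14 and 4.66 and p = 1e-04 each, the smallest that 10000 permutations can give. With like-named neighbours left out the liver pairs numbered 20, 19 and 12.

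**Figure D5:**
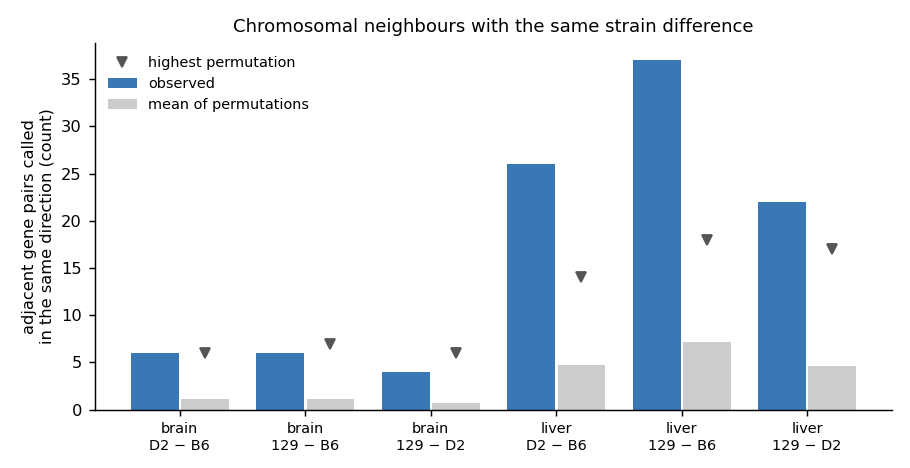
Bars give the adjacent gene pairs called in the same direction (blue) and the mean over 10000 permutations of the calls (grey), with triangles at the highest permutation, for each pair of strains and tissue. The 37 liver pairs of 129S2 and B6 exceed the highest permutation of 18.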

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

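Chosen only after the result was seen were the tests of a mislabelled array, of noise, of RNA from more than 1 strain, of a single B6 array, of RNA quality and of gene families.

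The strain difference changed between stages for 669 genes in brain and 4176 in liver, and between tissues for 681 genes. Among the 12 brain genes named for their F values, Pttg1 had the widest range of a strain difference across stages (5.19), followed by Gdpd3 and H2-Q2 (both 3.35), Rmst (2.83), S100a5 (2.39), Car8 (2.07), Prune2 (1.90), Efhd2 (1.79), Gnb1 (1.75), Neat1 (1.58), Cfap54 (1.5) and Fcrls (1.42). For the 12 liver genes named in the same way the range was 6.49 for Cyp2b9, 5.57 for Cyp2c39, 5.54 for Rassf4, 4.46 for Cox6b2, 3.99 for Pttg1, 3.93 for Gdpd3, 3.70 for Nnmt, 3.50 for Fmn2, 3.12 for Klrd1, 2.82 for Adh6-ps1, 2.65 for Serpina1c and 2.17 for Elovl3. A test of the difference itself brought out each of these. The files hold no detection calls, so signal near background may affect these ranges and their order. The interactions compare sets that were normalized apart, so a scale that differs between sets may also affect their ranges and counts.

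For every strain count, of 60 splits only 1, the real one, gave as many genes, which argues against chance division of the arrays. With 60 splits per count chance is not excluded. The margin was narrow in E14.5 brain, where the highest other split gave 697 and the real count without B6 replicate 3 was 683. The highest other split gave 71, 70 and 13 genes in brain for D2 against B6 (real 178), 129S2 against B6 (179) and 129S2 against D2 (151), and 86, 88 and 112 in liver (355, 431 and 358). For single stages from E14.5 to P90 it gave 697, 142, 97 and 271 in brain (real 858, 350, 334 and 451) and 651, 1236, 872 and 812 in liver (1025, 1700, 1408 and 1509). For the interactions it gave 384 in brain (669), 243 in liver (4176) and 23 between tissues (681).

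P90 brain replicate 2 of 129S2 lay between its own strain and the others, with r = 0.35 where the other arrays of the group had at least 0.76. A full swap of labels would shift strain markers by about 1, but markers higher in 129S2 shifted by 0.51, which argues against a mislabelled array. Noise is argued against by the lower of the shifts of both marker classes, which exceeded the highest of the other 71 arrays by 0.35. Markers lower in 129S2 shifted by 0.27 more than markers higher in it, which does not set this array apart, since elsewhere a single class reached 0.97 while the lower of both was at most 0.16. RNA of more than 1 strain in the sample or a heterozygous animal stays open, as both classes moved part of the way (0.78 and 0.51), and no breeding record in the labels bears on it.

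In E14.5 brain, cell cycle genes were higher than in B6 in D2 (20 of 32) and 129S2 (13 of 32), and synapse genes were lower in D2 in 4 of 26 cases and in 129S2 in 0 of 26. A single array may carry much of this, since of 20 cell cycle genes called between D2 and B6 only 4 were called without B6 replicate 3, and of the 4 synapse genes 2, with the synapse median at -0.10 in place of -0.27. Ribosomal protein genes of that array lay at -0.66 from the mean of the set, which is consistent with a lower RNA yield or quality. An older embryo cannot be told apart, since the slope of its deviation on the difference between P1 and E14.5 was 0.12 with r = 0.19 across genes, which are not independent. A true strain difference in developmental timing stays open and untested.

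Neighbouring genes were called in the same direction more often than permuted calls. With like-named pairs left out the highest permutation p of the 3 liver comparisons was 0.002, which argues against like-named neighbours as the whole cause. Related genes with unlike names, such as Mcpt8, Ctsg and Gzmb or Ifi204 and Mndal, were not left out. Gene families that share probes therefore stay open. Of the neighbour-pair genes with a second probe set, 61.7% had it called the same way, against 44.2% of other called genes. These shares pool 3 comparisons that repeat some genes, and in 129S2 against D2 they were 50% and 45.5%. Strain variants under the probes stay open, since variants of a segment could lie under both probe sets of a gene. Shares of cell types cannot be told apart, as 25.2% of the liver genes of such pairs were called the same way in brain, against 24.2% of other called genes. Copy number or regulatory differences of the segment could also move neighbours together, and the data used here held no genotype to test this.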

How the results depend on the processing

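Chosen only after the result was seen were the values as deposited, the filter at the median of each set and the list tests at each stage. Planned limma tests across stages and tissues were not run, nor their trended variance, array weights, replicate block, arrays in the fit or omission of a fold minimum, because separate normalization of each set leaves no valid error across sets. Of 123 named strain results 116 were called under every alternative that tested them, but 31 of the 123 were left untested by at least 1 alternative because they fell below its filter, and 85 were tested and called under all. With the mean of the probe sets of a gene, 6 of the other 7 were not called. These were Pdxdc1 in brain and liver, Prune2 in brain, and H2-D1 in brain, which reversed to 0.17 for D2 against B6. The remaining 1 was called in the opposite direction (H2-D1 in liver, 0.96). The mean cannot change the size of a gene with a single probe set, so shares of the 123 understate its effect on genes with several. With that mean 36 of the 123 moved by more than 1.5 times, and 0 did under any other alternative that tested them. They belong to Pdxdc1, H2-D1, Prune2, Hddc3, Soga3, Gabra2, Wdfy1, Galc, Rmst, Fam168a, Grik1, Gnb1, Neat1, Car8, Efhd2, Xaf1, Pik3ap1, Ang, Trim30d, Ctse, Slc15a2 and Rassf4. Xaf1 shrank from 2.90 to 0.78 in D2 liver against B6, Slc15a2 from 2.87 to 1.13 in 129S2 liver against D2, Galc from -2.51 to -0.78 in 129S2 brain against B6, and the range of Car8 from 2.07 to 0.59. The cause was not tested. Of 165 list tests 35 passed, all 35 also after median centring and 0 with an estimated correlation. Signal near background limits weak genes.

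With all probe sets, 731, 712 and 674 probe sets were called in brain (D2 against B6, 129S2 against B6, 129S2 against D2), 2266, 1186, 1098 and 1330 at the 4 stages in order and 1346 for the interaction. In liver these were 803, 873 and 820, then 1934, 3957, 2609 and 2745, then 7663, and 1492 differed between tissues. The stage differences became 9285 (P90 and E14.5), 2247 (P1 and E14.5), 446 (P7 and P1) and 5591 (P90 and P7) in brain and 9082, 3576, 484 and 4748 in liver, and the tissue differences 9917, 11186, 11762 and 12826 from E14.5 to P90. More features were tested there. In the strain pairs, 236, 234 and 242 brain genes had another probe set called where the main one was not, and 176, 159 and 195 liver genes. The counts by gene thus also depend on the choice of probe set.

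Without a fold minimum, the counts were 2069, 1795 and 1552 in brain, 2799, 799, 831 and 1242 at its stages, 3427, 3352 and 3659 in liver, 2488, 4376, 3557 and 3015 at its stages, 4224 between tissues, and 665, 712 and 569 shared by brain and liver. Where a second probe set also had to be called, they were 32, 28 and 18 in brain, 177, 65, 56 and 99 at its stages and 90 for the interaction, and 63, 66 and 57 in liver, 172, 307, 256 and 380 at its stages and 1005 for the interaction. Only genes with several probe sets enter there.

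With only the arrays compared, the E14.5 brain count was 253. A stricter filter gave 298 at P90 in brain and 1267 between P90 and P7 in brain, with fewer genes tested. Array weights gave 1389 for the brain interaction. As deposited, P90 differed from E14.5 in 6914 brain and 9384 liver genes and from P7 in 5514 and 7002. With like-named neighbours left out, liver pairs numbered 19 for 129S2 against B6 and 12 for 129S2 against D2. Except where the construction shows it, the cause was not tested.

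Leaving out each array in turn moved 1 of 29 gene counts by more than 1.5 times, that of E14.5 brain, from 683 without B6 replicate 3 to 1336 without B6 replicate 1. In brain the ranges were 170 to 179, 175 to 189 and 142 to 159 for the strain pairs, 324 to 371 at P1, 307 to 354 at P7, 401 to 534 at P90 and 529 to 944 for the interaction. In liver they were 342 to 375, 420 to 441 and 344 to 372, then 916 to 1103, 1455 to 1964, 1257 to 1544 and 1428 to 1535, and 3862 to 4349, with 660 to 704 between tissues.

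Replicate numbers were not taken to pair brain and liver samples, since the labels name no shared animal and only 19 of 36 pairs of the same number correlated above 0.1 (lowest -0.16). The median was 0.13 against -0.05 for other numbers, and 19 of 36 arrays were closest to their own number, so shared animals stay open. With the replicate number as a block, 177, 179 and 152 genes were called in brain, 870, 349, 332 and 454 at its stages and 631 for the interaction, 355, 431 and 358 in liver, 1029, 1712, 1414 and 1513 at its stages and 4191 for the interaction, and 687 between tissues. The block moved no count by over 1.5 times.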

Other observations

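Every list test at a single stage given here was chosen only after the result was seen. In liver at P90, clock genes set 129S2 apart. Dbp, a clock output factor, was 5.25 ± 0.33 higher than in B6 (3 arrays each) and 4.52 ± 0.33 higher than in D2, Tef was 1.76 and 1.52 higher, and the core activator Arntl was -1.98 and -2.26. Against B6, 9 of 16 clock genes were higher and 4 lower (10 higher adjusted over the list alone, median 0.73, adjusted p = 9.21e-05, and adjusted p = 0.0911 with an estimated correlation), and against D2 8 were higher and 4 lower (median 0.71, adjusted p = 4.93e-04, and adjusted p = 0.119 with an estimated correlation). Heat shock genes were lower in the same livers, in 5 of 13 cases against B6 (6 adjusted over the list alone, median -0.57, adjusted p = 6.87e-08, and adjusted p = 0.183 with an estimated correlation) and 7 of 13 against D2 (median -0.69, adjusted p = 5.45e-09, and adjusted p = 0.138 with an estimated correlation), with Hspb1 at -2.79 and -1.77. The labels give no hour of sampling. Fatty acid oxidation genes such as Acot1 (1.75) were higher than in B6 in 6 of 20 cases (median 0.47, adjusted p = 6.87e-08, and adjusted p = 0.183 with an estimated correlation). The acute phase genes Saa1 and Saa2 were lower than in B6 in 129S2 (-4.16 and -4.21) and D2 (-3.40 and -3.78), where 8 and 6 of 18 acute phase genes were lower and, in D2, 1 higher, but without B6 replicate 3 the lower genes numbered 4 in each comparison.

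In liver at E14.5, 11 of 11 neutrophil and myeloid precursor genes were lower in D2 than in B6 (median -1.84, adjusted p = 4.58e-16, and adjusted p = 0.0911 with an estimated correlation), with the granule genes Camp (-2.62), S100a8 (-2.39) and Ngp (-2.25), and 10 of 28 plasma protein genes were lower (median -0.39, adjusted p = 5.85e-17, and adjusted p = 0.0862 with an estimated correlation), such as haptoglobin Hp (-1.58). Without D2 replicate 3 these counts were 8 and 7. At P7, 10 of 11 neutrophil genes were lower in 129S2 than in B6 (median -1.45, adjusted p = 1.55e-13, and adjusted p = 0.119 with an estimated correlation), among them Ctsg (-2.12) and Mpo (-2.00). Cholesterol synthesis genes were lower than in B6 at P7, in 13 of 20 cases in D2 (14 adjusted over the list alone, median -0.91, adjusted p = 1.69e-13) and 7 of 20 in 129S2 (11 adjusted over the list alone, median -0.67, adjusted p = 9.07e-08), with Msmo1 at -2.46 in D2 and Idi1 at -2.13 and -1.92. These had adjusted p = 0.315 and 0.531 with an estimated correlation. In D2 against B6 at P7, 11 of 22 erythroid genes were also lower and 1 higher (13 and 2 adjusted over the list alone, median -0.79, adjusted p = 1.09e-05, and adjusted p = 0.732 with an estimated correlation). The lower ones numbered 5 without D2 replicate 3 and 16 without B6 replicate 2.

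In E14.5 brain the embryonic globins Hbb-bh1 (2.42 and 2.48) and Hba-x (1.74 and 1.44) were higher in D2 and 129S2 than in B6. B6 replicate 3 of that group stands apart, with cell cycle genes at -1.06 and ribosomal protein genes at -0.66, and without it the differences were 1.90 and 1.96 for Hbb-bh1 and 1.43 and 1.13 for Hba-x. Of 20 erythroid genes 3 were higher and 0 lower in D2 (median -0.14, adjusted p = 0.911) and 3 higher and 1 lower in 129S2 (6 lower adjusted over the list alone, median -0.22, adjusted p = 0.108). These counts rest on single arrays, with 7 lower in 129S2 without B6 replicate 1 and 5 without B6 replicate 3, and 5 higher in D2 (median 0.22) without B6 replicate 2.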
